A study of Drosophila melanogaster with 2 samples.

How the data were processed

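Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was carried out with an anti-GFP antibody on whole fruit fly prepupae of both sexes that carried CG8216, also named spab, fused to eGFP, per the labels. Prepupae are animals at the start of metamorphosis. The labels give an age of 24 days for this stage, where hours may be meant, as well as sonication to 200 to 800 bp, and 2 biological replicates. There is 1 group and no other condition. The comparisons therefore run between the replicates, between bound sites and the genome, between gene groups and other genes, and between genome builds.

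Per the deposited file list, each replicate has a relaxed list of peaks and background made from its own alignment and 1 control alignment, a further relaxed list was made from both replicates pooled, and a list thresholded on the irreproducible discovery rate (IDR) was derived from these. Each list exists on dm6 and on dm3. The aligner, the peak caller, their versions and the IDR threshold are not given in the sources used here. The value used to rank peaks is the peak signal deposited by the authors, in the caller's own units, whose scale is not stated. The lists also carry the authors' −log10 q value, which was at its ceiling in 92.8% of the IDR peaks and was not used for ranking. Across 5621 IDR peaks the pooled signal divided by the sum of the replicates' signals had a median of 1.00 (quartiles 0.988 and 1.02), so the signal adds up over libraries. Signals printed for different lists, as for the replicates or the builds, are not scaled for read number. All 5944 IDR peaks on dm6 were the 5944 highest-signal peaks of the pooled list of 30000. Depth is unknown, since the files give no read counts. Confidence intervals on shares are exact (Clopper-Pearson, 95%) and cover counting error over peaks or genes only. The control libraries and signal tracks were not used here.

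Positions are 1-based. The reference was Release 6 of the genome (dm6) with Ensembl release 115 gene models (FlyBase 6.54), so everything that needs genes or sequence was run on dm6, over chromosomes X, 2L, 2R, 3L, 3R and 4. The dm3 lists gave only counts, ranks and replicate comparisons, and no coordinate was converted between builds. A gene was called bound when an IDR summit lay within 500 bp of one of its annotated transcription start sites, and such peaks are called promoter peaks. Every summit was placed in the earliest class that applied: promoter, 5′ UTR, coding, 3′ UTR, other exon, intron, intergenic. Annotated transposable elements were left out of the gene models.

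Replicates were compared through the 5944 strongest peaks of each, matched when summits lay within 100 bp, and through Spearman and Pearson correlations across IDR peaks found in both, with 1000 bootstrap draws for the interval. Shares of summits were tested with two-sided exact binomial tests against shares of bases, gene groups with two-sided Fisher's exact tests against the remaining protein-coding genes (for RNA genes, against all remaining genes), and median signals with a two-sided permutation test of 100000 resamples. Motifs and all 8192 7-mers, with strands merged, were tested with an exact McNemar test of the 200 bp around each summit against 200 bp centred 500 bp away, the side alternating from peak to peak. Families of tests were adjusted by Benjamini-Hochberg, with a threshold of 0.05. Peaks and genes are not independent replicates, so these tests describe the authors' list and not the spread between animals.

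The 28 gene lists, the 26 motifs, the tests, the alternatives and the naming rule were fixed before the data were examined. Lists were defined by symbols or by patterns on symbols. 10 symbols were matched through synonyms and 5 were not matched. The pattern for replication-dependent histones, symbols beginning with His and a digit, also took 4 genes outside the histone cluster, which is stated with its result. The rule named every protein-coding gene bound by one of the 20 strongest peaks, the 5 strongest peaks with no start site within 500 bp, up to 4 members with the strongest promoter peak in each list past the threshold, spab itself, the motifs past the threshold, and the 5 7-mers with the largest ratio among those in at least 2% of summit windows. Other names in the text were chosen after their values were seen.

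Alternatives were the 2972 strongest IDR peaks, each replicate's own 5944 strongest peaks in place of the IDR list, other promoter, matching, pairing and motif windows, interval overlap, protein-coding start sites only, other backgrounds, and dm3. After the data were examined, 3 were added: a single summit per chain of summits within 500 bp, an expectation from 7-mers of the same GC content (for a motif, its GC percentage rounded to bases out of 7, whatever its length), and leaving out the histones. Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9 were used. On simulated data, 5944 random positions gave 0 of 8192 7-mers, 0 of 26 motifs and 0 of 7 location classes past the threshold. These positions were drawn evenly over the genome, without the richness in A and T found at summits. They do not show how many calls composition alone would give. Of 20 7-mers planted in 5% of the random windows, 20 were recovered, and 152 others were called beside them. Simulated lists with an odds ratio of 4 were called in 79 of 100 cases over 20 runs, and 2 of 400 unchanged lists were called. The 5 raised lists were drawn from the larger ones. Their rate therefore does not cover short lists, such as the 12 glial markers or the 11 ecdysone synthesis genes.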

Results

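Genomic sites bound by CG8216-eGFP, the product of the gene spab tagged with green fluorescent protein, were mapped in whole prepupae from 2 biological replicates. The reproducible list on dm6 held 5944 peaks with a median width of 460 bp. Each replicate's own list, and the list of both pooled, held 30000 peaks that include background. Signal in the reproducible list ran from 149.5 to 4074 in the caller's units, with a median of 278. Read depth is unknown.

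The strongest sites recurred in both libraries. At Ugalt, which encodes a UDP-galactose transporter, the strongest summit of the list had a signal of 2132 in replicate 1 and 1957 in replicate 2. In an intron of ush, a cofactor of GATA factors, the values were 1858 and 1867. Of the 5944 strongest peaks of replicate 1, 78.5% (95% CI 77.5 to 79.6%) had a summit within 100 bp of one among the 5944 strongest of replicate 2, and 78.5% held in the other direction, where uniform placement gives 0.894%. Both replicates held a matching summit for 5621 reproducible peaks (94.6%), and 13 peaks had none in either. The reproducible list was derived from these same replicates, so such matches were partly built in, and no chance rate was computed for them. Across those 5621 peaks, which are not independent replicates, signal had a Spearman rho of 0.864 (bootstrap 95% interval 0.854 to 0.874) and a Pearson r of 0.895 on the log scale. The log2 ratio of replicate 1 to replicate 2 had an SD of 0.44 and a median of −0.16, so replicate 1 was lower. With only these 2 libraries there was no test across animals.

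**Figure D1:**
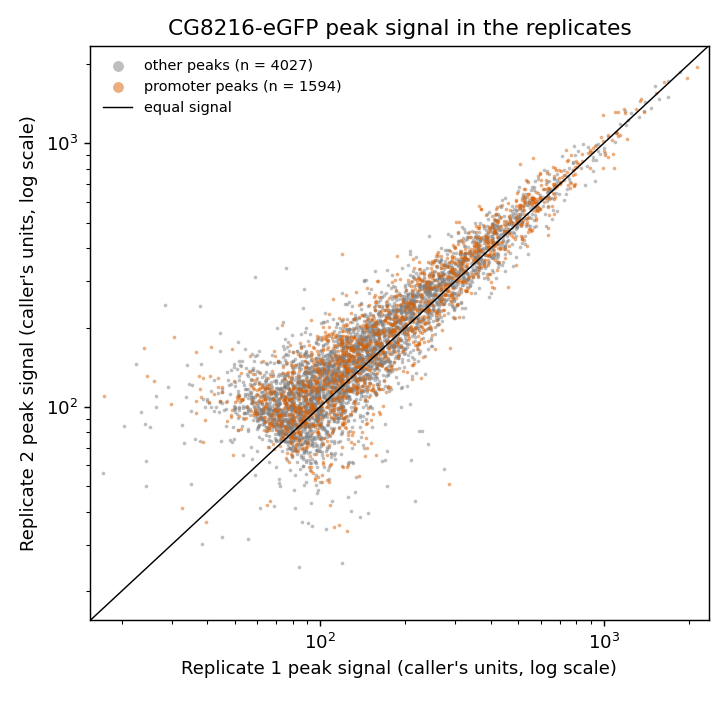
Peak signal in replicate 1 (x axis) and replicate 2 (y axis), both in the caller's units on log axes, for the 5621 reproducible peaks matched in both. Orange points are promoter peaks, grey points other peaks, and the line marks equal signal. Spearman's rho was 0.864.

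Among the 20 strongest peaks, start sites of 9 protein-coding genes were bound. Ugalt (FBgn0024994) held the peak at X:2703658–2704124, 27 bp from the nearest annotated start site, with a signal of 4074. CG14100 (3L:19590412–19590840) followed with 3747, and scb, which encodes an integrin alpha subunit, with 3320 at 2R:15248257–15248847. The others were larp, an RNA-binding protein (3090), the mitochondrial polynucleotide phosphorylase PNPase (2823), CG18549 (2788), CG13921 (2710), and Chro and Ssl1 (2508). Chro, a chromatin protein, and Ssl1, a TFIIH subunit, shared a single summit, 3L:22878688–22879108. Away from start sites the strongest peaks lay in introns of ush (2L:480847–481351, signal 3746), CG11050 (2L:6612461–6612937, 3419), dnr1 (2R:22569709–22570529, 3190) and CG32772 (X:4909941–4910840, 3064). The remaining distal peak fell in an exon of lncRNA:Vinr (X:12750798–12751681, 3264), 517 bp from the nearest start site. For each of these peaks both replicates had a matching summit, with signals between 1176 and 2132.

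Summits lay at promoters and in introns, and almost never in coding sequence. Promoters held 1723 of 5944 summits (29.0%, 95% CI 27.8 to 30.2%) against 13.6% of bases, 2.14-fold more (exact binomial adjusted p = 1.99e-209). Coding sequence held 10 summits where 817 were expected from its 13.7% of bases, a fold of 0.0122 (95% CI of the share 0.0807 to 0.309%), with an exact binomial p that computed to 0. The 3′ UTRs held 39 summits, 0.148-fold the expected number (exact binomial adjusted p = 2.16e-68). Introns held 2851 (48.0% against 39.5% of bases, exact binomial adjusted p = 1.41e-39), non-coding exons 72 (1.48-fold, adjusted p = 0.00178) and intergenic sequence 1213 (20.4% against 27.1%, adjusted p = 4.84e-33). The 36 summits in 5′ UTRs beyond the promoter window did not differ from expectation (exact binomial adjusted p = 0.140). The median distance from a summit to the nearest start site was 1708 bp. Bases are the background here, so mappable sequence and open chromatin were not taken into account. The 200 bp around summits outside promoters held 35.4% G and C, against 42.1% at random positions outside promoters.

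**Figure D2:**
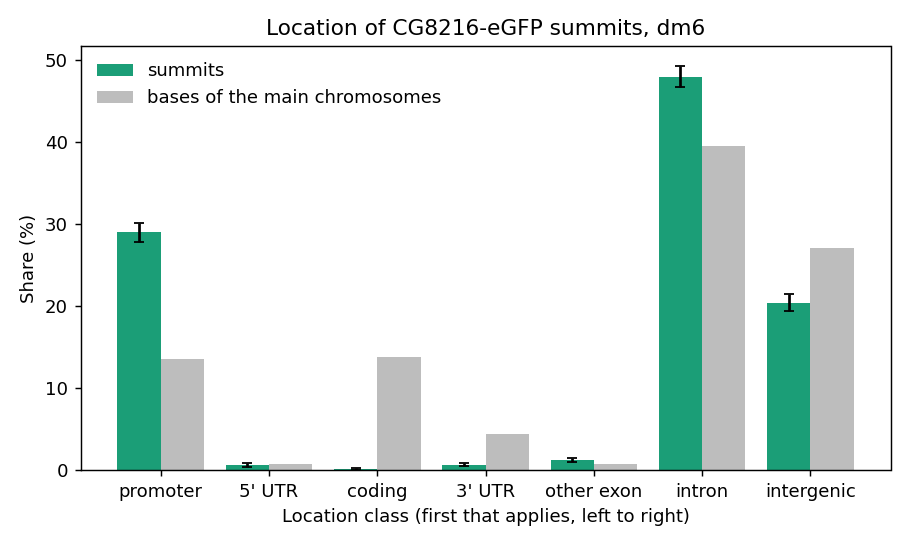
Share of the 5944 summits (green, with 95% exact binomial intervals) and of main-chromosome bases (grey) in each location class, in percent. Promoters held 29.0% of summits and 13.6% of bases, and coding sequence 0.168% of summits and 13.7% of bases.

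Promoter peaks were stronger than the rest. Their median signal was 308 (quartiles 205 and 582, n = 1723), against 267 (193 and 434, n = 4221) for other peaks. The ratio of medians was 1.15 (two-sided permutation p = 1e-05, the smallest that 100000 resamples can give). Among the 1188 strongest peaks 40.4% (95% CI 37.6 to 43.3%) were promoter peaks, and among the 1189 weakest 25.3% (22.9 to 27.9%). Genes that face another protein-coding gene head to head within 1000 bp were bound in 595 of 4650 cases (12.8%, 95% CI 11.8 to 13.8%), as for the pair Chro and Ssl1. Other protein-coding genes were bound in 923 of 9295 (9.93%, 9.33 to 10.6%), giving an odds ratio of 1.33 (Fisher's exact p = 4.37e-07). A shared summit counts for both genes of a pair, so the genes of a pair are not independent. A gene in a pair can also be called bound through a peak at its neighbour's start site. This alone could raise the odds ratio and was not separated from a preference for such promoters.

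Chromosome 4, the small and largely heterochromatic autosome, was nearly free of peaks. It held 7 summits where 59.2 were expected from its bases, a fold of 0.118 (exact binomial adjusted p = 8.99e-17). Arm 3L held 1423 (1.14-fold, exact binomial adjusted p = 7.15e-08) and arm 2R 989 (0.880-fold, adjusted p = 1.13e-05). Arms 2L (1077, exact binomial adjusted p = 0.291) and 3R (1368, adjusted p = 0.121) did not pass the threshold. The X held 1080 summits, 18.2% (95% CI 17.2 to 19.2%) against 17.6% of bases (adjusted p = 0.264), and 270 of its 2196 protein-coding genes were bound (12.3%), against 1248 of 11749 autosomal ones (10.6%, Fisher's exact p = 0.0228). In a pool with equal numbers of both sexes the X has 3 copies for every 4 of an autosome, which the shares of bases leave out. The X share was 17.1% among the 2972 strongest peaks, below the share of bases, and against the share of protein-coding genes its excess passed the threshold (1.15-fold, exact binomial adjusted p = 7.60e-07). Against that background 3R also passed, with fewer summits (0.938-fold, exact binomial adjusted p = 0.00764). The call on 2R was lost among the 2972 strongest peaks (exact binomial adjusted p = 0.135).

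Of 13945 protein-coding genes 1518 (10.9%) were bound, and 7 of the 28 fixed gene lists passed the threshold, or 6 with the histone cluster left out. Genes of the ecdysone response, the steroid program that drives metamorphosis, were bound in 12 of 31 cases (38.7%, 95% CI 21.9 to 57.8%; odds ratio 5.20, two-sided Fisher's exact adjusted p = 0.000289). The strongest promoter peaks among them were at E23, an ABC transporter gene (2L:3354893–3355321, signal 609 in replicate 1 and 673 in replicate 2), and at the pro-apoptotic gene hid (3L:18185756–18186188, 579 and 604). The next were Eip93F, a transcription factor gene (3R:21972095–21972459, 464 and 459), and Eip75B, a nuclear receptor gene (3L:17999612–17999824, 313 and 386). The other bound members were EcR and usp, the subunits of the ecdysone receptor, and br, Eip74EF, Eip63E, Hr78, ftz-f1 and Ldh. A gene counts as bound through any of its start sites, and gene length and number of start sites were not matched for this list. In gene bodies, against lists matched on length, ecdysone response genes held 87 summits where the median was 52. That difference did not pass (permutation adjusted p = 0.271). Whether gene length or more start sites account for the excess at promoters was not tested. None of the 11 ecdysone synthesis genes was bound (95% CI up to 28.5%, Fisher's exact adjusted p = 0.757).

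Cytoplasmic ribosomal protein genes were bound in 30 of 93 cases (32.3%, 95% CI 22.9 to 42.7%; odds ratio 3.96, Fisher's exact adjusted p = 5.71e-07). Their peaks were of moderate signal. The strongest, at RpS27 (3R:25247384–25247632), lay 4 bp from the nearest annotated start site, with 270 in replicate 1 and 196 in replicate 2. It ranked 1444 in the list. Those of RpLP0 (3L:22075975–22076178, 231 and 198) and RpL34b (3R:9401084–9401543, 225 and 193) had matches in both replicates. At RpS4 (3L:13041702–13041910) replicate 2 had 257 and replicate 1 no summit within 100 bp. Mitochondrial ribosomal protein genes were bound in 8 of 73 cases (11.0%, Fisher's exact adjusted p = 1). The odds ratio of the cytoplasmic list rose to 5.90 with a promoter window of 250 bp and to 8.12 by interval overlap. With the 2972 strongest peaks alone it was 2.09 and the call was lost (Fisher's exact adjusted p = 0.0916).

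Chemoreceptor, cuticle, snoRNA and tRNA genes were bound less often than other genes. Gene length and number of start sites were not matched in this comparison. In gene bodies, against lists matched on length, chemoreceptor genes held 0 summits where the median was 13 (permutation adjusted p = 0.00250). Cuticle genes held 2 where it was 6, which did not pass (permutation adjusted p = 0.515). RNA genes were not compared in this way, and whether their annotated starts are separate promoters was not examined. Chemoreceptor genes (odorant, gustatory and ionotropic) held 1 bound member of 180, Gr77a (3L:20739318–20739777; 0.556%, 95% CI 0.0141 to 3.06%; Fisher's exact adjusted p = 5.71e-07). Cuticle protein genes held 1 of 122, Cpr72Ea (3L:16362020–16362479; 0.820%, 0.0208 to 4.48%; Fisher's exact adjusted p = 0.000175). Of 274 small nucleolar RNA genes 5 were bound (1.82%, 0.595 to 4.21%; Fisher's exact adjusted p = 1.17e-06), the strongest at snoRNA:U49:66Da (3L:8600915–8601062, signal 359). Peaks at snoRNA:Me28S-A774b (198), snoRNA:Psi18S-176 (184) and snoRNA:Psi18S-920 (162) were weaker, and the last had no matching summit in either replicate. The snoRNA odds ratio of 0.165 was 0.0642 without replicate 2 (2 bound) and 0.527 with a promoter window of 1000 bp (21 bound), and the call stayed in both cases. Of 295 tRNA genes 15 were bound (5.08%, 2.87 to 8.25%; Fisher's exact adjusted p = 0.0126), led by tRNA:Tyr-GTA-1-8 (3R:8669199–8669532, signal 1253), tRNA:Gln-TTG-2-1 (598), tRNA:Lys-TTT-1-1 (460, with no match in replicate 2) and tRNA:Pro-AGG-1-2 (388). The tRNA odds ratio was 0.478, and 0.483 with the 2972 strongest peaks, where fewer genes were bound and the call was lost (Fisher's exact adjusted p = 0.0916). With a promoter window of 1000 bp it was 0.668 and the call was also lost (Fisher's exact adjusted p = 0.110).

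Histone genes passed the threshold with 2 of 115 bound (1.74%, 95% CI 0.211 to 6.14%; Fisher's exact adjusted p = 0.00189). The bound members, His3.3B (X:9155176–9155379) and His2Av (3R:26866537–26866996), encode replication-independent variants and lie outside the histone cluster. The cluster itself (2L:21416953–21541681), a tandem repeat with 111 of the members, held 0 summits of the reproducible list. It also held 0 of the 30000 pooled peaks, where 28.0 were expected from its length, so the pooled list has no peak of any strength in it. The list therefore gives no measure of binding at the cluster genes. The call was lost when the peak interval had to cover the start site (Fisher's exact adjusted p = 0.0594), at an odds ratio of 0.144 in both cases, and without replicate 1 only 1 member was bound (odds ratio 0.0644).

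The remaining lists did not pass the threshold, after adjustment over all 28. Notch-responsive E(spl) genes were bound in 4 of 11 cases (Fisher's exact adjusted p = 0.0862) and glial markers in 4 of 12 (adjusted p = 0.105). The E(spl) list passed with the 2972 strongest peaks (Fisher's exact adjusted p = 0.0249) and with a window of 1000 bp (adjusted p = 0.0413). Close to start sites the excess was mostly gone, with 1 of 11 bound in a window of 250 bp (odds ratio 1.21, Fisher's exact adjusted p = 0.859) and by interval overlap (1.65, adjusted p = 0.886). With the window of 1000 bp the proteasome list passed as well, as bound less often (1 of 48, odds ratio 0.130, Fisher's exact adjusted p = 0.0413). Fat body genes were bound in 4 of 16 cases, heat shock genes in 6 of 27, architectural and core promoter proteins in 5 of 27, and muscle genes in 5 of 28. Developmental transcription factors had 5 bound of 35, translation initiation factors 5 of 44, and cell cycle and replication genes 3 of 34. Oxidative phosphorylation genes had 4 bound of 84, neuronal markers 1 of 24 (elav), haemocyte markers 1 of 14 (ush), proteasome genes 1 of 48 (Rpn5), testis-specific genes 1 of 40 (Mst87F) and snRNA genes 1 of 32 (snRNA:7SKa). No member was bound among 29 spliceosomal genes (95% CI up to 11.9%), 22 glue and prepupal secretion genes (15.4%), 20 antimicrobial peptide genes (16.8%) and 8 Hox genes (36.9%). In the lists other than E(spl) and glia the adjusted p lay between 0.158 and 1.

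**Figure D3:**
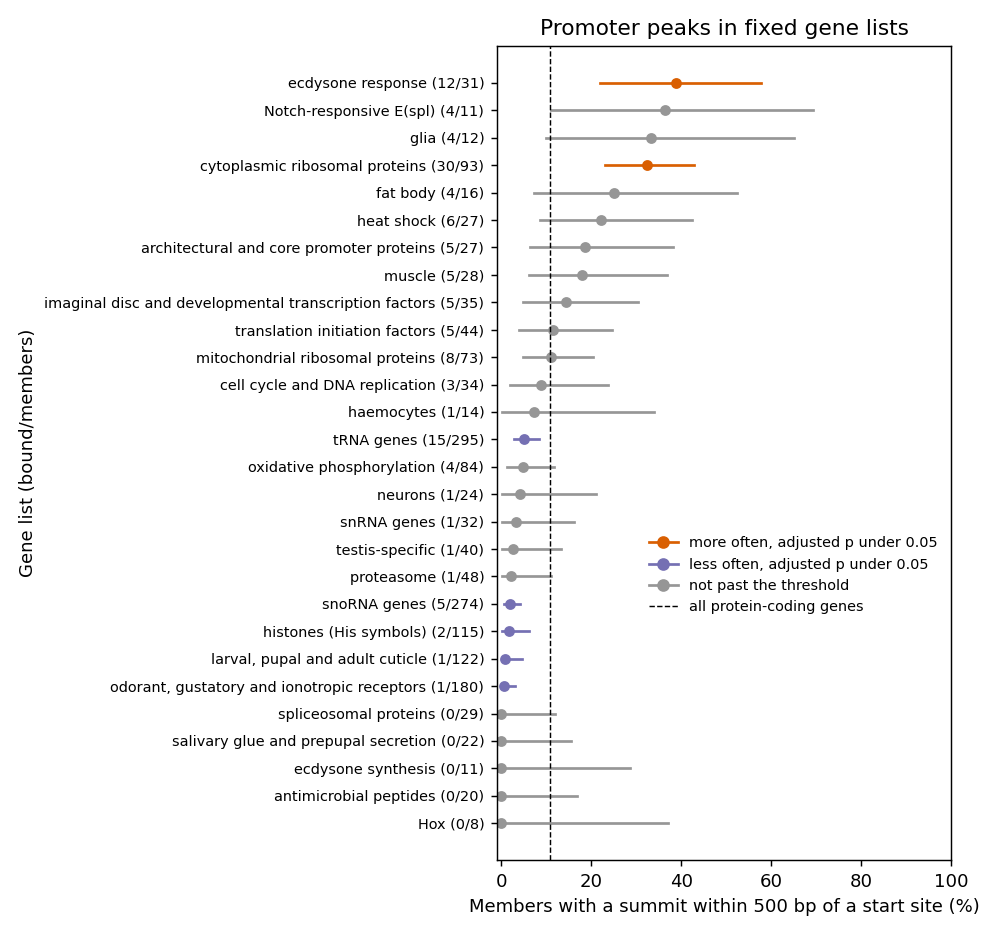
Share of members bound (x axis, percent) in each of the 28 gene lists (y axis, with bound and total members), with 95% exact binomial intervals. Orange lists were bound more often and purple lists less often than other genes at the threshold; the dashed line marks the 10.9% of all protein-coding genes, and tRNA, snRNA and snoRNA lists were compared with all genes.

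The tagged gene itself carried no peak. No reproducible summit lay within spab (FBgn0033358, 2R:8963164–8968184, reverse strand) or at its promoter, and neither the replicate lists nor the pooled list had a summit inside it. Within 20 kb of the gene 4 reproducible summits were found (95% Poisson interval 1.09 to 10.2), where uniform placement gives 2.00. The nearest lay in flz, 9590 bp from the spab start site, and ranked 4994 of 5944. The other 3 lay in lncRNA:CR44274, CG8229 and babo.

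Among words in at least 2% of summit windows, CAGTGTA and CACTGAG were the most raised, and the others of the leading 5 overlap or resemble them. CAGTGTA occurred in 7.45% of summit windows and 1.56% of flanks, a ratio of 4.76 (exact McNemar adjusted p = 1.51e-54), and CAGTGCA in 10.6% and 3.40%, a ratio of 3.13 (adjusted p = 1.14e-52). The words CACTGAG (ratio 4.16, exact McNemar adjusted p = 1.03e-44), AGTGTAC (3.48, adjusted p = 1.11e-19) and ACTGAGA (3.16, adjusted p = 4.41e-30) complete the leading 5. Without replicate 1 CACTGAG came before CAGTGTA, with ratios of 4.48 and 4.36. In all, 4269 of 8192 7-mers passed the threshold, 1407 more frequent at summits and 2862 less. Summits were rich in A and T (67.0% in the 20 bp to the left of the summit against 54.9% in the 20 bp that begin 300 bp to its left), which moves most words. Against 7-mers of the same GC content 1126 passed, 610 more frequent and 516 less. Words with as many G and C bases as CAGTGTA had a median ratio of 0.947, and those with as many as CAGTGCA 0.716.

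The CAGTG words were most frequent beside the summit, a feature examined after these values were seen. With windows of 100 bp the ratios of CAGTGTA and CAGTGCA were 2.98 and 2.05. Within 200 bp of summits CAGTGYA, where Y is C or T, had 2041 matches. The matches on the forward strand lay to the right of the summit in 841 of 1065 cases (79.0%), and those on the reverse strand to the left in 772 of 976 (79.1%). Read along the motif, 1613 matches lay downstream of the summit (79.0%, 95% CI 77.2 to 80.8%; exact binomial p = 3.86e-161), at a median of 88 bp (quartiles 62 and 119 bp). Neighbouring summits and matches are counted separately in this test.

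**Figure D4:**
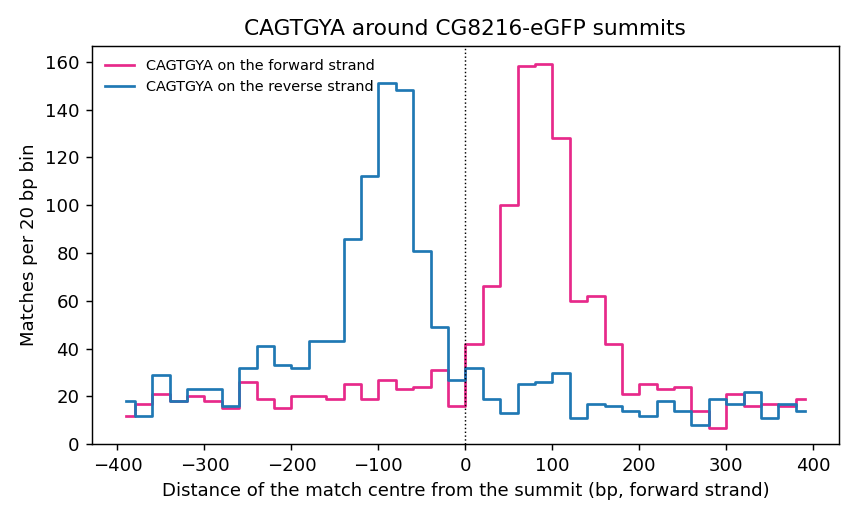
Number of CAGTGYA matches per 20 bp bin (y axis) against the distance of the match from the summit in bp along the forward strand (x axis), over 5944 summits. Matches on the forward strand peak at 159 per bin to the right of the summit and those on the reverse strand at 151 to the left.

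Of 26 fixed motifs 10 passed the threshold. More frequent at summits than in flanks were Mef2 (11.1% against 6.11%), TATA box (4.27% against 2.44%), Ohler motif 6 (3.18% against 1.87%), Forkhead (12.6% against 8.82%), homeodomain (15.3% against 11.6%), GATA (17.5% against 13.3%) and initiator (45.8% against 41.0%), with exact McNemar adjusted p between 4.87e-21 for Mef2 and 1.64e-05 for Ohler motif 6. Less frequent were the Ftz-f1 site (0.303% against 1.01%, exact McNemar adjusted p = 6.41e-06) and the E-boxes CACGTG (1.40% against 2.59%, adjusted p = 1.22e-05) and CAGCTG (6.39% against 9.59%, adjusted p = 5.04e-10). The CAGCTG call was lost with windows of 400 bp (16.6% against 18.1%, exact McNemar adjusted p = 0.0594). The EcR/usp element occurred in 1 summit window and 8 flanks (exact McNemar adjusted p = 0.0923). The GAGA motif was at 4.06% of promoter summits against 2.09% of their flanks, and at 1.94% of other summits against 2.89%. That difference between promoter and other peaks passed an exact test (Fisher's exact adjusted p = 0.000283), as did that of CAGCTG (adjusted p = 0.00714). Against 7-mers of about the same GC percentage, whose length differs from most motifs, 6 motifs passed, of which Mef2, Forkhead and Ftz-f1 kept their direction while homeodomain was then less frequent than expected. MTF-1 (exact binomial adjusted p = 2.56e-15) and Ohler motif 7 (adjusted p = 2.11e-06) were above that expectation. Against flanks MTF-1 turned with the window, less frequent with 100 bp (5.87% against 8.60%, exact McNemar adjusted p = 5.88e-08) and more frequent with 400 bp (32.1% against 28.7%, adjusted p = 0.000152). With unbound promoters as the control 5 passed, of which GATA and Ftz-f1 kept their direction. The strongest was GAGA, in 4.06% of bound and 1.51% of unbound promoters (Fisher's exact adjusted p = 0.000157). DRE and Ohler motif 1 were less frequent. Bound windows were centred on summits and control windows on start sites. Of 1723 promoter summits 1342 lay more than 100 bp from the nearest start site. This offset holds for all 5 motifs. Their differences, including the higher share of GAGA and the lower shares of DRE and Ohler motif 1, were not separated from it. Against their own flanks, promoter summits held DRE in 1.68% against 0.871%, which did not pass (exact McNemar adjusted p = 0.106).

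Processing on the earlier build dm3 gave 7124 reproducible peaks, 1.20 times the number on dm6. The ratio was between 1.14 on chromosome 4 (8 against 7 peaks) and 1.22 on 3L (1736 against 1423), so the additional peaks were spread over all arms. They came with a lower minimum signal, 122 against 149.5, and 5800 dm3 peaks reached the dm6 minimum. On dm3, 4 peaks lay outside the main chromosomes. No test was made, since the libraries are the same.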

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

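The motif CAGTGYA, the ranks below the reproducible list and the comparison with promoter initiators were chosen after the 7-mer result was seen. The pooled peaks beyond the reproducible list were not searched for motifs in the report, and they held CAGTGYA more often than their flanks. Within 100 bp of the summit it was found in 14.7% of peaks ranked 5945 to 10000 (95% CI 13.6 to 15.8%; flanks 4.59%). The share was 12.1% at ranks 10001 to 15000 (flanks 4.50%), 9.78% to rank 20000 (4.62%), 8.66% to rank 25000 (5.26%) and 7.40% to rank 30000 (4.48%). Each excess over the flank passed an exact McNemar test, the weakest with p = 3.73e-11 and 3.44e-10 at the last ranks.

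In the reproducible list 17.2% of summit windows held CAGTGYA (1022 of 5944), against 4.96% of flanks, with a share of 19.1% at most in any of 5 groups of the list by signal, and 16.9% in the strongest group. The base composition of summits does not give this excess: random intron and intergenic windows of the same GC content held CAGTGYA in 4.70%, against 19.1% (95% CI 18.0 to 20.4%) of summits outside promoters. At promoter peaks it was in 12.4% (10.9 to 14.1%). This does not settle whether an initiator-like element is involved there. Of 1723 promoter summits 1342 lay more than 100 bp from the nearest start site, so most windows did not reach one. Of the 1022 summits with a match 808 lay more than 500 bp from any annotated start site. Initiators of annotated promoters do not account for those 808. Annotated transposable elements held 0.0978% of the summits with a match, 1 of 1022, so nearly all of these summits lie outside annotated copies. Only 10 of all 5944 summits lay in such elements, to which short reads map poorly. Copies with no called peak are therefore not covered. Whether CG8216 binds this sequence, or it marks sites where the tagged protein is brought by another factor, stays open as a hypothesis, and no biological explanation was tested.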

How the results depend on the processing

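The single-summit, same-GC and histone alternatives were chosen after the results were seen. Of 60 alternative values for the results that answer a comparison, 46 kept their direction and side of the threshold, or, for counts of peaks, lists, motifs and 7-mers, stayed within 1.5 times the reported count whichever members passed. Of 108 for single classes, lists and 7-mers 104 did. The replicate overlap and rank correlation, which had no test, were held to their 95% intervals over peaks, not to a spread between animals. All 7 alternative values fell outside. Replicate overlap was 85.4% with any 1 bp overlap, 66.3% within 50 bp, 83.9% for the 2972 strongest peaks and 76.4% on dm3. The rank correlation was 0.850, 0.885 within 50 bp and 0.852 on dm3, the first with 1 bp overlap. The X share, not past the threshold, fell below its expectation at 17.1% in the 2972 strongest peaks. It ran from 17.4% to 18.6% with a replicate left out, below expectation without replicate 1 and past the threshold without replicate 2 (exact binomial adjusted p = 0.0497). Against genes, 18.2% was past it. Motifs fell from 10 to 5 (promoter control, fewer windows) and 6 (same GC), and 7-mers from 4269 to 1126 (same GC). In the other settings motifs rose to between 11 and 13, and 7-mers lay between 3251 (2972 strongest peaks) and 4322; the cause of the others was not tested. Of the 7 gene lists 5 were kept with the 2972 strongest peaks; lists lost are named in the report. The rank of the tagged locus on dm3 was not run. No paired analysis was possible because there is 1 group. Unknown depth limits what a missing peak shows.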

Other observations

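The strand context of CAGTGYA, the comparisons with constitutively expressed genes and the value without E2f1 were chosen after the results were seen. Certain long genes held many peaks, and clustering within single genes was not tested. Of 13945 protein-coding genes 1664 (11.9%) held a summit in the gene body, and 46 held 10 or more. kirre (X:2740384–3134532) held 28 over 394 kb (0.710 per 10 kb), sbb (2R:18278198–18357296) 25 over 79.1 kb, and Tet (3L:2786207–2879158), which encodes a dioxygenase of the TET family, 25 over 93.0 kb. Higher densities were found in Mnt, a partner of Max (15 summits, 5.02 per 10 kb), and in the cell cycle regulator E2f1 (16 summits, 3.94 per 10 kb). Compared with 10000 random lists matched on gene length, 4 of 25 lists differed. Neuronal genes held 6 summits where matched lists had a median of 37 (permutation adjusted p = 0.0100), with no summit in Appl and 2 in dlg1. Chemoreceptor genes held 0 against 13 (permutation adjusted p = 0.00250), ribosomal protein genes 16 against 2 (adjusted p = 0.00250), and cell cycle genes 22 against 6 (adjusted p = 0.0463). At a median length of 1.32 kb, ribosomal protein genes have bodies close to their start sites. Their excess in bodies is not separate support for that at promoters. Without E2f1 the cell cycle list held 6, within the middle 95% of matched lists (0 to 10). Ecdysone response genes held 87 against 52 (permutation adjusted p = 0.271).

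Around 1164 CAGTGYA matches within 100 bp of summits, the bases before the motif were rich in T. T stood at 70.1%, 73.1% and 70.5% at positions −7, −6 and −5 from the C of the motif, and C and T together dominated positions −4 to −2, while the bases after the motif were mixed. At promoter summits the match lay on the strand of the nearest gene in 182 of 324 cases (56.2%, 95% CI 50.6 to 61.7%; exact binomial p = 0.0301, unadjusted). Annotated transposable elements, which short reads map to poorly, held 10 summits (0.168%) for 5.94% of bases.

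The near absence of summits from coding sequence is the deviation from the genome background with the most peaks missing. Composition may account for part of it, since random positions outside promoters held 15.9% coding sequence, and 5.17% once matched to the GC content of summits. That is still above the 0.237% (95% CI 0.114 to 0.435%) of summits outside promoters. A calling or mapping step that leaves out coding sequence would apply to weak peaks too, and 3.94% (3.42 to 4.52%) of the 5000 lowest pooled peaks lay in it. This is above the 0.168% of the reproducible list but far below the 13.7% of bases. It excludes only a step that leaves out coding sequence altogether. A step that lowers signal there would move coding peaks to lower ranks, and the share was 0.616% at ranks 5945 to 10000. Such a step stays open as a part or the whole of the cause, since the controls were not used. With 1 group no biological explanation was tested.

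The excess at ribosomal protein genes could come from constitutive expression alone. Mitochondrial ribosomal, proteasome and oxidative phosphorylation genes were bound in 6.34% of 205 cases (95% CI 3.42 to 10.6%), and in 7.34% of 177 (3.97 to 12.2%) without duplicated copies, many of them testis-type, which argues against this. Shared promoters do not account for all of it: of 38 ribosomal protein genes with no head-to-head neighbour 23.7% were bound, against 9.87% of 9257 other such genes (Fisher's exact p = 0.0104). Very high transcription, which may favour recovery of DNA in ChIP whatever the protein, stays open, since no untagged sample was analysed here.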
